A study of Lotus japonicus with 14 samples.

How the data were processed

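RNA was measured in 14 libraries of the legume Lotus japonicus, 1 library per condition. Wild type plants (accession MG20, Miyakojima) and plants of the mutant apn1, labelled Fix-, were either left uninoculated or inoculated with Mesorhizobium loti. The sample titles spell the mutant differently from the study design, and the design's spelling, apn1, is used. Each genotype had 1 uninoculated root library and nodule libraries from 2 rhizobial strains, MAFF303099 and TONO, at 5, 7 and 10 days after inoculation (dai). Per the labels' protocols, nodule primordia and young nodules were cut from the roots, ribosomal RNA was depleted with kits for plants and for gram-negative bacteria, and libraries were made with a ScriptSeq version 2 kit. The groups were taken from the sample titles.

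The authors deposited 12 tables, each of which sets 1 nodule library against the uninoculated root library of the same genotype over 38476 gene models. Per the file headers, each table holds the original read count of both libraries and a normalized value made with the iDEGES/DESeq procedure. The submitters' processing notes name Bowtie2 2.0.2 and DESeq. The genome build, the annotation, the counting tool and whether strand was used in counting are not given in the sources used here, so overlapping, antisense and near-identical gene models may share reads. In each deposited table the normalized signal equalled the count divided by 1 size factor per library, and the factors were set within that pair of libraries. The normalized values of different tables are therefore on different scales, and all tests across tables were run on the deposited counts. The counts of each root were identical in the 6 tables that contain it, and each root was used once. No column was left unmapped.

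The gene models carry identifiers only. None of the 38476 identifiers matched the gene name table supplied for this species, which belongs to the assembly LjGifu_v1.2, so no gene names are given. All 28 gene lists fixed before the data were examined had 0 matched members. The tests of these lists and their response per library were not run, and the gene that is mutated in apn1 was not analysed here. The rule for named genes, fixed before the data were examined, was at most 2 identifiers that rose and 2 that fell per contrast. They were those with the largest fitted change among genes past the threshold with the same direction on all days, or in all pairs of libraries. Any other identifier in the text was chosen after its values were seen.

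The tests had been planned with limma on log2 values. Because the tables hold whole-number counts, edgeR's quasi-likelihood test with TMM scaling was used in its place, as had been set out for that case (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0; figures with Python 3.11.15 and matplotlib 3.10.9). Genes with a mean count of at least 10 after scaling to equal totals were tested, which left 32549 genes in the 12 nodule libraries and 32777 in all 14 libraries. The nodule model had 4 genotype-strain combinations and 3 days as additive terms, with 6 residual degrees of freedom. The model of all 14 libraries added the root as a level, with 7 residual degrees of freedom. No condition has a replicate library. The p-values therefore treat the 3 days as blocks, assume that day effects are alike in all combinations, and measure only what the additive terms leave over. In the model of all 14 libraries both roots share 1 level without a day. The roots differ in genotype, so their spread includes the genotype. The biological coefficient of variation estimated in this way was 22.7% for the nodule libraries and 22.3% for all libraries. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 were counted as changed. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its quasi-likelihood F statistic. Values per library are log2 CPM (counts scaled to a common library total) after TMM scaling with a prior count of 2.

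The total count per library ran from 33981124 to 58395305. A count of 0 allows up to 3 counts, which is 0.051 to 0.088 CPM per library. Where all libraries of a group were at 0, a lower bound of the fold was computed from pooled counts, with 3 counts over the group. Ratios of pooled counts carry an exact 95% binomial interval, and shares of counts carry a 95% Wilson interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

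The models were tested on simulated counts drawn from the real library sizes and dispersions and 1 real mean per gene over all libraries. In these, 100 genes were changed 2-fold and 100 changed 4-fold. Each comparison was simulated once. The simulated counts held no other effect of day, strain or genotype and no departure from the additive terms. The shares below therefore do not give the power or the error rate where the additive terms fail. For apn1 against wild type under TONO, 38% of the 2-fold and 77% of the 4-fold changes were recovered among 32549 genes, and 3 unchanged genes were called. For the genotype by strain interaction the shares were 3% and 61%, with 4 unchanged genes called. For 10 against 5 dai they were 47% and 90%, with 9 unchanged genes called. For a term for the apn1 TONO library of 10 dai alone they were 2% and 45%, with 1 unchanged gene called. For nodules against roots, over 32777 genes, they were 43% and 85%, with 7 unchanged genes called.

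In regroupings of the libraries, all 35 or 10 possible splits were fitted, or 40 were drawn with a fixed seed where more exist, to limit the time. Alternatives covered upper-quartile scaling, the deposited size factors, filters on low counts, limma with 3 pseudocounts, DESeq2, other day terms, libraries paired by strain and day, subsets of libraries, and leaving out each day and each library. The mean genotype contrast over both strains, the term for a single library, the lists of late genes and the share of root-silent genes were added after the data were seen.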

Results

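The series followed root nodule development in Lotus japonicus, a model legume, in wild type plants and in the mutant apn1, labelled Fix-. Nitrogen fixation was not examined here with either strain, so this label was not checked for each strain. Nodules formed with 2 strains of the symbiont Mesorhizobium loti, MAFF303099 and TONO, were collected at 5, 7 and 10 dai, and an uninoculated root of each genotype served as the control. Each of the 14 conditions was measured in 1 library, so no value has a replicate error of its own. The root libraries held 52272951 and 54816945 counts, and the nodule libraries 51189011 to 58395305 at 5 dai and 48180653 to 55377555 at 7 dai. The 10 dai libraries were shallower, at 33981124 to 37261815 counts, so that day and total count changed together. These totals are counts on the gene models. The number of reads sequenced was not used here, and depth below means these totals.

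Nodules were first compared with uninoculated roots, as the mean of the 4 genotype-strain combinations against both roots. This mean does not test whether a change is common to both genotypes and both strains. Tissue, inoculation and age cannot be told apart here, since the roots were uninoculated and have no day. The most strongly raised gene models were LjT06N06.290.r2.d and LjSGA_039331.1, which had 0 counts in both roots. LjT06N06.290.r2.d had 5773 to 23228 counts in the 12 nodule libraries, at least 7836-fold higher than in roots. LjSGA_039331.1 had 2007 to 14355 counts, at least 7078-fold higher. Conversely, chr6.CM0437.390.r2.m had 2497 and 2684 counts in the roots and 10 counts over all 12 nodule libraries, a ratio of 2706 (95% interval 1470 to 5647). Of the 10 counts 6 came from wild type with MAFF303099 at 7 dai. With 1 day or 1 library left out the log2 fold change ran from −13.53 to −11.80, against −12.10 in the main fit. LjSGA_056821.1 had 223 and 464 counts in the roots and 1 count over the nodules, in wild type with TONO at 7 dai, a ratio of 3588 (642 to 141938). Its log2 fold change was −11.02, and −10.32 without the wild type root, which held the 464 counts. These 4 gene models, located by their identifiers only, had edgeR adjusted p-values of 6.31e-08, 2.30e-07, 8.72e-08 and 5.50e-05 in that order. Each went the same way in 12 of 12 nodule libraries, as the rule for named genes requires.

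Across the transcriptome, 14881 of 32777 genes differed between nodules and roots (edgeR quasi-likelihood, adjusted p under 0.05), 7189 higher and 7692 lower in nodules. Among them 3446 were at least 2-fold higher and 4061 at least 2-fold lower, and 10545 went the same way in all 12 nodule libraries. Comparisons within a genotype share 1 root, so part of this agreement is built in, and no value for unchanged genes is given for it. Wild type nodules had 1291 genes at least 2-fold above their root in all 6 libraries and 1837 at least 2-fold below it. For apn1 the numbers were 1440 and 1869. Since the 6 comparisons of a genotype share 1 root, unchanged libraries were simulated against it, which gave 103 higher and 17 lower genes for wild type and 92 and 28 for apn1. In both genotypes together, 873 genes were higher and 1240 lower in this way. Within the 12 deposited tables, each normalized separately, a median of 9916 genes were at least 2-fold apart on the log2 scale with a pseudocount of 2. Without the wild type root, 9608 genes passed in place of 14881.

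The share of counts from gene models that were silent in roots followed nodule age. There were 10160 gene models under 1 CPM in both roots. They held 0.229% of the counts of the wild type root and 0.237% of those of the apn1 root. With MAFF303099 their share was 2.63%, 7.59% and 7.99% at 5, 7 and 10 dai in wild type and 2.04%, 6.80% and 7.25% in apn1. With TONO it rose to 8.74% in wild type, from 1.48% at 5 dai and 5.73% at 7 dai. In apn1 with TONO it was 1.55%, 4.93% and 4.01%, so that the value at 10 dai was lower than at 7 dai. The 95% Wilson intervals reached at most 0.0093 percentage points to either side.

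**Figure D1:**
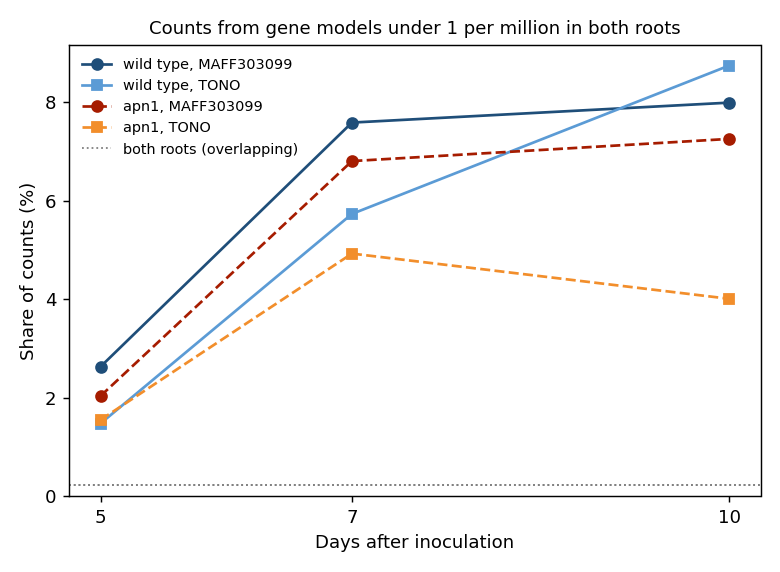
Share of each nodule library's counts, in percent, that came from the 10160 gene models under 1 CPM in both roots, against days after inoculation. Each point is 1 library; the apn1 TONO library stands at 4.01% at 10 dai, against 7.25% to 8.74% in the other 3 libraries of that day.

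The change with nodule age was tested as 10 dai against 5 dai over all 4 genotype-strain combinations. LjSGA_143580.1 had 0 counts in all 4 libraries of 5 dai and 79 to 2126 counts at 10 dai, at least 3002-fold higher over the pooled libraries. The lowest of these values, 79, was that of apn1 with TONO. The gene model chr1.CM0171.270.r2.m rose from 56 counts over the libraries of 5 dai to 111958 at 10 dai (log2 fold change 12.05, SE 0.60, edgeR adjusted p = 8.52e-07). Of the 56 counts 39 came from wild type with MAFF303099, and without that library the log2 fold change was 13.05. In the other direction, chr5.CM0311.230.r2.d had 25 to 60 counts per library at 5 dai and 0 at 10 dai, at least 33.8-fold lower (edgeR adjusted p = 0.00189). LjSGA_032630.1 fell from 277 to 395 counts per library to 0 in 3 libraries and 5 in apn1 with TONO, a pooled ratio of 139 (95% interval 59.6 to 430). Without the apn1 TONO library of 10 dai its log2 fold change was −11.10, against −7.05 with it. The direction was the same in 4 of 4 combinations for each of the 4 genes, as the rule for named genes requires. With day as a linear number chr1.CM0171.270.r2.m missed the threshold (adjusted p = 0.0728, log2 fold change 7.51), 1 of its 24 alternatives, and the other 3 genes passed in all of theirs.

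Of 32549 genes tested in nodules, 14912 differed between 10 and 5 dai, 7621 higher and 7291 lower at 10 dai, and 13957 of them went the same way in all 4 combinations. At 7 against 5 dai, 6430 genes differed, 3437 higher and 2993 lower. With upper-quartile scaling 6742 genes were higher and 7988 lower at 10 dai, and with DESeq2 8176 and 7972. With the deposited size factors 3410 were higher and 14140 lower, with a median over all genes of −0.40 on the log2 scale. These factors are set within each table and were not rescaled between tables, so this run mixes scales and cannot test the balance of directions. In wild type libraries alone 9930 genes passed, and in apn1 libraries alone 6601.

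Genes with a large late change under MAFF303099 were followed in the TONO libraries, a comparison added after the data were seen. The list of late rising genes held 901 genes at least 4-fold higher at 10 than at 5 dai in both genotypes with MAFF303099. Their median difference between apn1 and wild type under TONO was 0 on the log2 scale at 5 dai and 0.016 at 7 dai. At 10 dai the median was −1.45, with 89.2% of the genes lower in apn1 and 67.9% at least 2-fold lower. This median lay below that of all 10000 random lists matched on mean expression, which ran from −0.095 to 0.097. For the 2554 genes of a list made at 2-fold in place of 4-fold, which was not set against random lists, the median was −0.94, with 47.1% at least 2-fold lower. The 1116 late falling genes had medians of 0.027, −0.25 and 0.85 at 5, 7 and 10 dai, and 80.5% were higher in apn1 at 10 dai; with a list made at 2-fold, of 3373 genes, the median at 10 dai was 0.66. The median at 7 dai lay below and that at 10 dai above all of the random lists, which ran from −0.039 to 0.064 and from −0.040 to 0.17. Genes chosen for a shared change may move together, which random lists do not allow for. A place outside the random lists, for rising or falling genes, therefore gives no error rate. Leaving out genes with 3 counts or fewer in either library gave −1.43 for the late rising genes and 0.74 for the late falling genes at 10 dai. With counts under 3 set to 3 the medians were −1.45 and 0.77. Under MAFF303099, from which the lists were made, the medians at 10 dai were −0.13 and −0.10. Each of these comparisons sets 1 library against 1, with no replicate check.

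**Figure D2:**
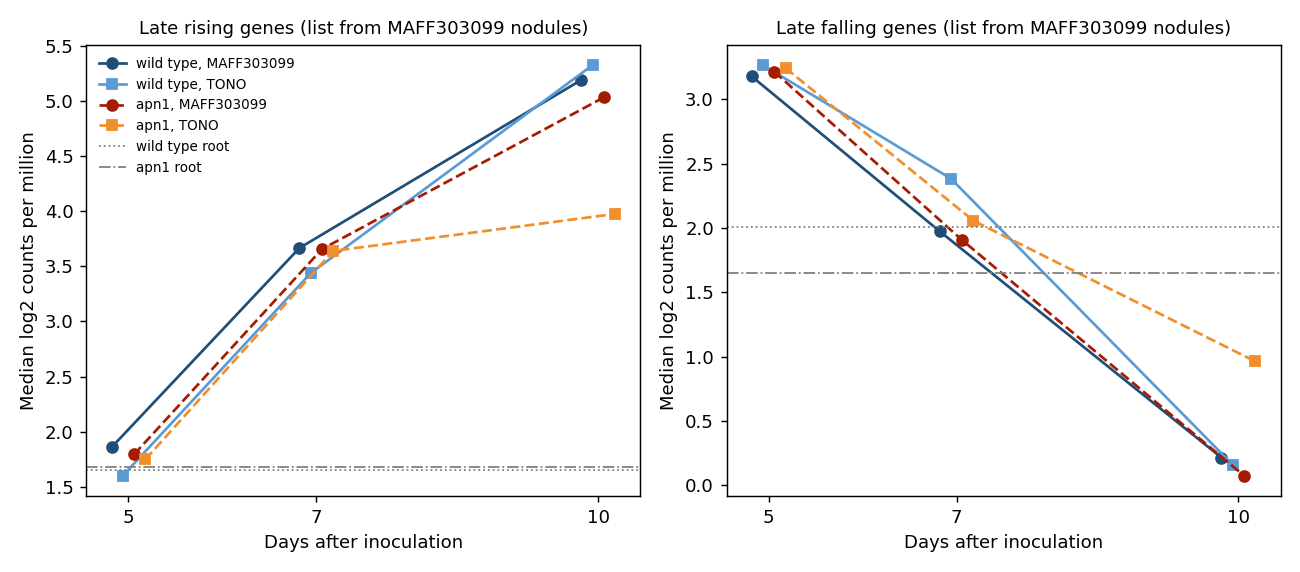
Median log2 CPM of 901 late rising genes (left) and 1116 late falling genes (right) in each nodule library against days after inoculation, with both uninoculated roots as horizontal lines; points of 1 day are set slightly apart sideways. At 10 dai the late rising genes had a median of 3.97 in apn1 with TONO and 5.03 to 5.32 in the other 3 libraries.

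Nodules of apn1 and wild type formed with TONO were then compared; the mutation was not separated from other differences between the plant lines. The gene model chr3.CM0005.530.r2.m had 0 counts in all wild type libraries and 110 to 152 counts in apn1 nodules with TONO, at least 116-fold higher (edgeR adjusted p = 0.0323). The level of chr4.CM0007.980.r2.a was raised in apn1 (log2 fold change 3.46, SE 0.30, edgeR adjusted p = 0.00472), from 155 to 187 counts per library to 1640 to 2685. Conversely, chr2.CM0065.440.r2.d had 55 to 103 counts in wild type and 0 in apn1, at least 96.8-fold lower (edgeR adjusted p = 0.0407). Its neighbour by number, chr2.CM0065.450.r2.d, was lower by a log2 fold change of −7.08 (SE 0.36, edgeR adjusted p = 8.98e-05), with 26 to 57 counts in apn1 against 3180 to 7671. All 4 differences had the same direction on 3 of 3 days, as the rule for named genes requires.

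In total, 20 of 32549 genes differed under TONO, 12 higher and 8 lower in apn1, and all 20 kept their direction on the 3 days. Without wild type with MAFF303099 at 10 dai 16 genes passed, 0 to 13 passed when any other nodule library or any day was left out, and 184 passed with DESeq2. Among the 25 alternatives tested for it, chr3.CM0005.530.r2.m missed the threshold in 14, and chr2.CM0065.440.r2.d missed it in 17 of 24. The corresponding number was 4 of 25 for chr4.CM0007.980.r2.a and 1 of 25 for chr2.CM0065.450.r2.d, and none of the 4 changed direction.

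Pair by pair, the 10 dai libraries of TONO nodules differed most between the genotypes. Of 32777 genes, 6759 were at least 2-fold apart, 3930 higher and 2829 lower in apn1, against 1786 at 5 dai and 2106 at 7 dai. With MAFF303099 the numbers were 1371, 1598 and 3694 at 5, 7 and 10 dai. The uninoculated roots of the 2 genotypes were at least 2-fold apart at 1809 genes, 1003 higher and 806 lower in apn1. These counts have no replicate check.

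**Figure D3:**
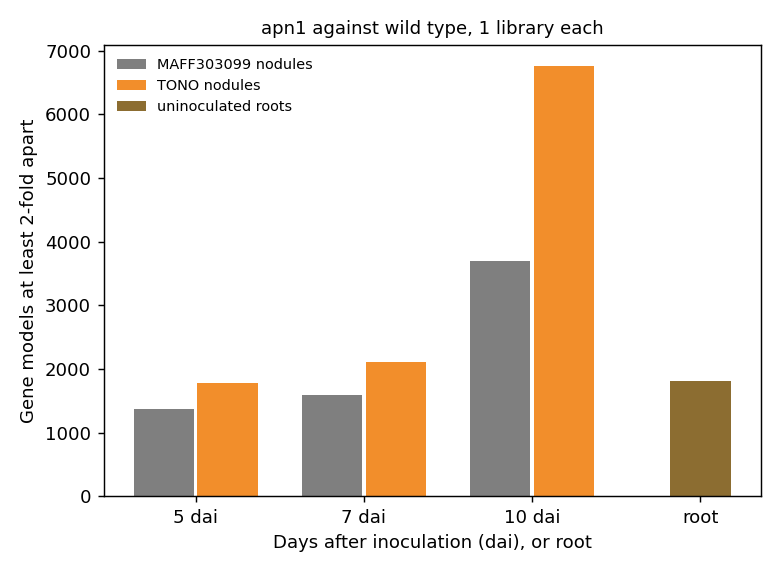
Number of gene models, of 32777, at least 2-fold apart between the apn1 and the wild type library of the same strain and day, and between both uninoculated roots. Each bar compares 1 library with 1; the bar for TONO at 10 dai stands at 6759 and that for MAFF303099 at 10 dai at 3694.

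The same comparison was made under MAFF303099. Again chr3.CM0005.530.r2.m was detected in apn1 alone, with 74 to 101 counts, at least 98.6-fold higher than in wild type (edgeR adjusted p = 0.0298). LjSGA_045610.1 was raised from 7 to 17 counts per library in wild type to 150 to 196 in apn1 (log2 fold change 3.97, SE 0.44, edgeR adjusted p = 0.0238). The gene model chr2.CM0065.440.r2.d had 86 to 116 counts in wild type and 0 in apn1, at least 91.1-fold lower (edgeR adjusted p = 0.0431). For chr2.CM0065.450.r2.d the log2 fold change was −6.40 (SE 0.35, edgeR adjusted p = 0.000173). All 4 had the same direction on 3 of 3 days, as the rule for named genes requires. Under the alternatives tested they missed the threshold in 13 of 25, 12 of 25, 15 of 24 and 1 of 25 in that order, and none changed direction.

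Altogether 17 genes differed under MAFF303099, 12 higher and 5 lower in apn1. Without wild type with TONO at 5 dai or at 10 dai, or apn1 with TONO at 5 dai, 16, 12 and 13 genes passed. Without apn1 with TONO at 10 dai 27 passed, 0 to 11 passed when any other nodule library or any day was left out, and DESeq2 gave 233. Of the 20 genes called under TONO and the 17 called under MAFF303099, 13 were shared, 8 higher and 5 lower in apn1 under both strains. Independent lists of these sizes would share 0.0104 genes. The 2 comparisons have no library in common but share 1 estimate of the spread.

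Averaged over both strains, a contrast added after the data were seen, 27 genes differed between apn1 and wild type nodules, 20 higher and 7 lower in apn1. Of these 27 genes, 25 differed in the same direction between the uninoculated roots, 17 of them by at least 2-fold. Without day 7 there were 3 genes, without day 10 16, without apn1 with MAFF303099 at 7 dai 17, and DESeq2 gave 267. By the same rule for named genes, LjSGA_012799.2 was also raised, with 8 to 448 counts in apn1 and 3 to 16 in wild type nodules (log2 fold change 4.04, SE 0.58, edgeR adjusted p = 0.0439). Among the 7 genes lower in apn1, 5 were numbered on the contig chr2.CM0065 of chromosome 2, which has 55 tested gene models. Chosen after their values were seen, they are the models numbered 400, 430, 440, 450 and 540. Model 430 had 90 to 227 counts in wild type nodules and 2 to 5 in apn1 nodules. Its counts were 320 in the wild type root and 4 in the apn1 root. Model 540 had 46 to 127 counts in wild type nodules and 0 to 6 in apn1, and 126 against 2 counts in the roots. For model 400 the log2 fold change was −2.56 (SE 0.22, edgeR adjusted p = 0.00166), with 58 against 25 counts in the roots.

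**Figure D4:**
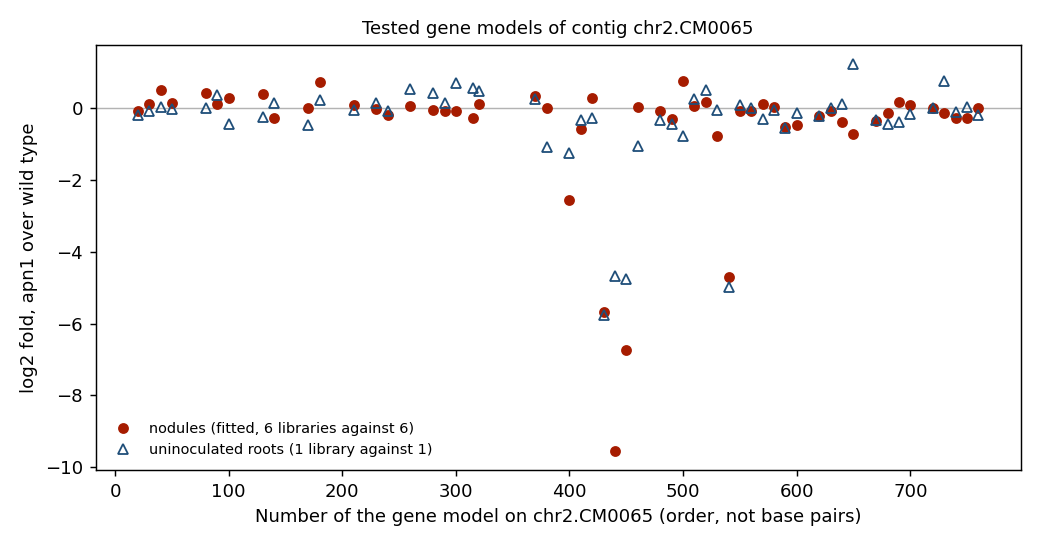
Fitted log2 fold of apn1 over wild type in nodules (filled circles, 6 libraries against 6) and the log2 difference between the uninoculated roots (open triangles, 1 library against 1) for 55 tested gene models of contig chr2.CM0065, in order of their number. Models 400, 430, 440, 450 and 540 lie below the rest in both tissues; the depth of model 440, at 0 counts in apn1 nodules, depends on the prior count.

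Whether the genotype effect differed between the strains was tested as the genotype by strain interaction. No gene passed the threshold with edgeR (0 of 32549, smallest adjusted p = 0.0567), and 2691 genes had an unadjusted p under 0.05. With limma 2 genes passed and with DESeq2 192. Without all libraries of 10 dai, 8 genes passed with edgeR, and without the apn1 MAFF303099 library of 10 dai 13 did. In simulated data the interaction test recovered 3% of 2-fold and 61% of 4-fold changes, so most 2-fold interactions were not detectable.

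Both strains were then compared within each genotype. In wild type, chr4.CM0126.1710.r2.a was higher with TONO, with 1447 to 2659 counts against 373 to 489 (log2 fold change 2.35, SE 0.28, edgeR adjusted p = 0.0252). The abundant gene model chr4.LjT13G24.180.r2.a was also higher with TONO (log2 fold change 2.05, SE 0.31, edgeR adjusted p = 0.0380), at 9857 against 2398 CPM over the pooled libraries. Lower with TONO were LjSGA_012776.1 (log2 fold change −1.65, SE 0.25, edgeR adjusted p = 0.0380) and chr1.CM0316.1120.r2.m (log2 fold change −1.46, SE 0.22, edgeR adjusted p = 0.0380). Each had the same direction on 3 of 3 days, as the rule for named genes requires. Among 24 alternatives they missed the threshold in 11, 13, 15 and 13, and none changed direction. In apn1 the fitted log2 differences of these 4 gene models were −0.48, −0.19, −0.44 and 0.05 in the same order. Their interaction terms had adjusted p-values of 0.0966, 0.309, 0.501 and 0.320 with edgeR.

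In wild type 85 genes differed between the strains, 66 higher and 19 lower with TONO. With the deposited size factors, not rescaled between tables and so on mixed scales, 46 passed, 29 higher and 17 lower. The number was 0 without any single wild type nodule library, day 5, day 7 or apn1 with MAFF303099 at 5 dai. It was 169 without day 10, 544 without the apn1 TONO library of 10 dai, 8 to 56 without each of the other 4 apn1 nodule libraries, and 1385 with DESeq2. In apn1, 0 genes differed between the strains with edgeR, with 1748 genes at an unadjusted p under 0.05, 0 with limma and 50 with DESeq2, and 1 gene passed with edgeR without apn1 with TONO at 10 dai. For the 85 genes of wild type, the median log2 difference was 1.10 in wild type and 0.05 in apn1 when signed as in wild type. These genes were chosen for their difference in wild type, which inflates 1.10.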

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

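The term for single libraries, the tests of uniform dilution by root tissue, of root-only genes and of genes above or below all other libraries, and the tests of contig chr2.CM0065 were chosen after the results were seen; the tests of depth, of values between roots and nodules, of younger nodules and of an equal strain difference were written after a first look at the files, in which the departing library had been seen, but before their own values, and the test of values between roots and nodules was for a time replaced after its result and then restored.

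A library was singled out because it departed from the additive effects of combination and day. A term for 1 library at a time was added to the nodule model. For apn1 with TONO at 10 dai, 1370 of 32549 genes passed an edgeR adjusted p under 0.05, 661 higher and 709 lower than the other 11 libraries predict. For each of the other 11 libraries 0 genes passed with edgeR, with 293 to 3005 genes at an unadjusted p under 0.05, against 6649 for apn1 with TONO at 10 dai. The departing library stays in those 11 fits and may widen their spread, so the terms were refitted without it. Leaving that library out did not bring genes past the threshold for any of these terms, and the spread itself was not compared. The terms for apn1 with TONO at 5 and 7 dai are then 1 and the same test, since only these libraries of the combination remain. A term for 1 library has little power, so these 0s do not show that the other libraries follow the additive terms. With each of the other 11 libraries left out in turn, 253 to 1790 genes passed for apn1 with TONO at 10 dai. DESeq2 and limma were run for this term only for apn1 with TONO at 10 dai and gave 2842 and 1500 genes, and edgeR gave 1343 with no filter on low counts and 1405 with upper-quartile scaling. Of the 1370 genes, 1187 departed by at least 2-fold. The condition has 1 library and no replicate, so the spread in its fit comes from the other libraries. The library was chosen for its departure, so this term describes the departure and is no independent test of it.

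Lower depth was argued against as the whole cause, since with all libraries thinned to the smallest total 6251 genes were at least 2-fold apart between the genotypes at 10 dai under TONO, against 3250 in the highest of the other 5 pairs. More root tissue was not excluded by the test written down before, in which 778 genes lay at least 2-fold outside the range of the roots and the other 10 dai nodules, against 702 for wild type with TONO. Tests chosen after that outcome argued against root tissue like the uninoculated roots as the whole cause: the root-silent counts would need a root share of 55.7%, while 58 genes of at least 10 CPM in both roots and at most 10% of that level in the other 11 nodule libraries had a median of 1.40% of their apn1 root level (0.085% to 1.48% over 9 definitions of such genes), and the log2 differences of 67 abundant root-silent genes had an interquartile width of 1.04, against 0.426 for 72 such genes under MAFF303099. Younger nodules, through a delay or a wrong day label, stay open, as 497 genes lay at least 2-fold outside the range of the other 7 and 10 dai nodules, fewer than the 685 of wild type with TONO; 183 genes lay at least 2-fold above each of the other 13 libraries, against at most 50 in the other 10 dai libraries and 145 in the apn1 root, but 102 lay below, against 185 to 420, and the sum of 285 against 470 in wild type with TONO, added to the rule after the 183 alone had argued against younger nodules, leaves this undecided. An effect of the combination of apn1 and TONO, which the design names, is a hypothesis that stays open. Over the 3 days its test was the genotype by strain interaction, which 0 genes passed with edgeR and 192 with DESeq2. An effect at 10 dai alone could not be tested, since 1 library cannot tell it from a departing sample. Root tissue that differs from the uninoculated roots stays open and untested.

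The second pattern is the contig chr2.CM0065, on which 5 of the 7 genes lower in apn1 lie. In 10000 random draws of 7 tested genes, 0 placed as many on 1 contig, and the largest number was 2. A change in nodules alone was argued against by the roots, where 5 of the 5 models were at least 2-fold lower in apn1, in 1 library per genotype. A contiguous deletion across all 5 models was argued against, because in nodules 9 of the 9 tested models numbered between them kept over 50% of the wild type level, and in roots 8 of the 9 did. Smaller deletions, or sequence differences between the plant lines that keep reads from aligning, could give such values and were not tested.

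The third pattern is the strain difference of 85 genes in wild type and 0 genes in apn1 with edgeR, where 1748 genes had an unadjusted p under 0.05 and limma gave 0 and DESeq2 50. With an equal strain difference in both genotypes, these genes would move in apn1 by about the wild type median of 1.10. Their median in apn1 was 0.0516, with an interquartile range from −0.11 to 0.26, which falls short of that prediction. The fitted difference kept its wild type sign in 52 of the 85 genes. On all 3 days 31 genes had the wild type sign and 11 the opposite one. The set was chosen for its difference in wild type, which inflates 1.10 and alone would give a lower median in apn1. The test therefore cannot tell an unequal strain difference from that choice. With edgeR the interaction passed for none of these genes. An unadjusted p under 0.05 was reached by 79 of them, a number that the same choice inflates. A response to the strain that depends on the genotype may be a hypothesis for replicated libraries.

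Other splits of the libraries show how many genes other groupings gave. For 10 against 5 dai, 1 of 35 splits, the real one, gave as many as 14912 genes, and the highest of the others gave 3. For apn1 against wild type over both strains, 1 of 40 splits drawn, the real one, gave as many as 27 genes and the highest other gave 3. Each is the smallest share that such splits can reach. In the other splits a real effect would enter the residual spread, so few calls there do not exclude chance on their own. For the interaction the real value and the highest of 40 splits drawn were both 0, and since no split can give fewer, this says nothing about chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 20 and 0 for the genotypes under TONO, 17 and 1 under MAFF303099, 85 and 0 for the strains in wild type, and 0 and 0 for the strains in apn1. Nodules against roots were not split because there are 2 roots.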

How the results depend on the processing

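The alternatives for both strains together, for the departure of 1 library, for late genes and for root-silent genes were chosen after the results were seen. Each condition has 1 library, so no replicate numbers pair the libraries. Paired by strain and day, with 6 pairs as blocks and 5 residual degrees of freedom, 24 genes differed between apn1 and wild type over both strains, 20 of them among the 27. Tests of gene lists, with either correlation or with fry, and the authors' adjusted p at other thresholds were not run, since no list had a matched member and the tables used here hold no adjusted p. The pseudocounts were tried with limma. Each root alone as the control is the same as leaving out the other root.

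Of 218 alternative values of the main counts, 139 stayed within the allowed factor and 79 were listed as moved. The factor was not applied to values made with another limit or definition, which were all listed as moved. These are the late gene lists, the root-silent share, the deposited tables at 4-fold and the genes at least 2-fold from the root in all 6 libraries. For all of the 79 the cause was not tested, except that subsets and left-out libraries hold fewer libraries. Of 488 values of named genes under alternatives, 358 kept their call, 130 lost it and 0 changed direction.

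When 1 day or 1 library was left out, the counts moved as follows. The 14881 genes between nodules and roots ranged from 9608, without the wild type root, to 17107, without day 10, and the 14912 genes between 10 and 5 dai from 11753, without day 7, to 15874, without apn1 TONO 10 dai. The 20 genotype genes under TONO ranged from 0 to 16, and only the run without wild type MAFF303099 at 10 dai, with 16, stayed near 20. The 17 under MAFF303099 ranged from 0, without day 7, to 27, without apn1 TONO 10 dai, and the 27 over both strains from 3, without day 7, to 32, with 16 without day 10 and 17 without apn1 MAFF303099 at 7 dai. In these runs the interaction gave 0 to 13 genes, and the strains in apn1 0 to 1, the 1 without apn1 TONO 10 dai. The 85 strain genes in wild type ranged from 0, without day 5, day 7, any wild type library or apn1 MAFF303099 at 5 dai, to 544, without apn1 TONO 10 dai. They were 169 without day 10, of which 59 were among the 85, and 8, 56, 17 and 13 without apn1 MAFF303099 at 7 and 10 dai and apn1 TONO at 5 and 7 dai. The 1370 genes that departed in apn1 TONO 10 dai ranged from 253, without apn1 TONO 7 dai, to 1790, without wild type TONO 5 dai, with 404 and 670 without apn1 TONO and apn1 MAFF303099 at 5 dai, and 849 and 853 without wild type MAFF303099 and TONO at 7 dai.

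DESeq2 called more genes: 184 and 233 for the genotypes under TONO and MAFF303099, 267 over both strains, 192 for the interaction, 1385 and 50 for the strains in wild type and apn1, and 2842 for the departure of apn1 TONO 10 dai. All 20, 17, 27 and 85 genes called with edgeR were among these. With limma the interaction gave 2 genes at each pseudocount. With the deposited size factors 46 strain genes were called in wild type, and the median log2 fold of all genes was 0.16 for the genotypes under TONO and for the interaction. These factors were not rescaled between tables, so the values come from mixed scales. With no day block the counts were 4 under TONO, 1 under MAFF303099, 15 over both strains and 0 for the strains in wild type. From TONO libraries alone 3 genotype genes were called, and from MAFF303099 libraries alone 1. For 10 against 5 dai, wild type libraries alone gave 9930 and apn1 libraries alone 6601. Genes at least 2-fold from the root in all 6 libraries numbered 3128 in wild type and 3309 in apn1. At 4-fold the deposited tables had a median of 3561.5 genes.

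With lists at 2-fold, late rising genes had a median of −0.94 and late falling genes 0.66. The root-silent share of apn1 over wild type at 10 dai under TONO was 0.459, and 0.488 or 0.545 with limits of 0.3 or 3 CPM. The 10 dai libraries were the shallowest, so depth limits low genes most on that day.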

Other observations

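All comparisons in this part were chosen after the data were seen. The course of the whole transcriptome with TONO can be set against that with MAFF303099. Across 32777 genes, which are not independent replicates, the log2 change from 5 to 10 dai in wild type with TONO had a slope of 0.99 on the mean change with MAFF303099 (Pearson's r across genes 0.82). For apn1 with TONO the slope was 0.66 (r 0.68). From 5 to 7 dai the slopes were 0.90 in wild type and 0.86 in apn1. Few gene models carried the root-silent share: at 10 dai, the 10 most abundant held 5.68% of all counts in wild type with TONO and 2.15% in apn1 with TONO, against 4.89% and 4.51% with MAFF303099.

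Of the 20 genes higher in apn1 over both strains, 11 were also at least 2-fold higher in the apn1 root. LjSGA_045610.1 had 10 counts in the wild type root and 378 in the apn1 root, chr4.CM0007.980.r2.a had 84 and 1414, and chr3.CM0005.530.r2.m had 0 and 166.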
